A study of Homo sapiens with 16 samples.

How the data were processed

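RNA-seq and ribosome footprints (Ribo-seq) were measured in WI-38 human lung fibroblasts, young or senescent, as control or after heat shock, with 2 libraries in each of 8 groups. The authors deposited RSEM expected counts per gene, which in the files were already whole numbers, for RNA-seq and Ribo-seq. The authors also deposited TPM, transcript levels that RSEM scales by effective gene length. The submitters' processing notes name STAR, RSEM, Bowtie2 and the build hg19; their roles, the gene annotation, trimming and the removal of ribosomal RNA reads are not given in the sources used here. RNA libraries were made with a kit for TruSeq RNA, and footprints were prepared with RNase If and a sucrose cushion, per the labels.

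The RNA-seq table listed 23597 genes, of which 5898 had 0 counts in all libraries, and for Ribo-seq 19201 were listed, of which 4549 had 0. Genes were kept by the identifiers of the tables, since 25 and 6 symbols occurred more than once. All 32 columns of values were used. Library totals are the sums of counts assigned to genes. Reads carry no molecular identifiers, so counting intervals would cover counting error only. With 2 libraries per group the spread was pooled over groups, which left 4 residual degrees of freedom per assay and 8 for both assays together.

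Expected counts were filtered with filterByExpr, scaled by TMM and fitted with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, with 1 mean per group. This tested 13177 genes in RNA-seq and 11288 in Ribo-seq. Translational efficiency was the footprint contrast minus the RNA contrast, from a fit of all 16 libraries over 11166 genes. The comparisons were heat shock against control in young and in senescent cells, the difference of these responses (senescent minus young), and senescent against young cells in control and under heat shock. Efficiency was not compared between senescent and young cells under heat shock. P values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Changes are relative to the scaled bulk of genes, so a change shared by all genes is not seen.

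Of the 26 gene lists, 25 had members in the tables. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry; p values were adjusted over the lists of a comparison. Camera called 130 of 327 list results. With an estimated correlation 7 were called, and these were the cytosolic chaperones on heat shock in both states in RNA and in footprints, their difference of response in RNA, and oxidative stress genes on heat shock in both states in efficiency. Fry called 34. The genes named in the text follow a rule: the 5 largest rises and 5 largest falls among called genes with a mean of at least 10 CPM, counts scaled to library size, in a group compared, up to 4 called members of each described list (or 2 abundant ones where none passed), and fixed panels of chaperones and senescence markers. Not all genes that the rule picks are named. Genes named beyond these were chosen after their values were seen. Genes with 0 to 3 counts over the libraries of a group compared are given by their counts, without a fold, apart from 1 fitted value in the closing section, named there as no bound.

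Same-numbered libraries were checked for pairing. Across genes, the difference of replicate 1 from replicate 2 correlated between RNA groups at 0.481 to 0.658 in the 6 pairs of groups, and between Ribo groups at −0.04 to 0.33. The same difference correlated between RNA and Ribo libraries of a group at 0.00798 in young control, 0.256 in young heat shock, 0.220 in senescent control and 0.492 in senescent heat shock. What the replicate numbers mark is not given in the sources used here, so counts are given also with replicate number as a block. Genes are not independent replicates in these correlations.

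The groups, comparisons, gene lists, rule for names and a first set of alternatives were fixed before the data were examined. The alternatives were relative log expression scaling, library size only, no filter on low counts, the block, DESeq2 1.42.0, limma-trend on log2(TPM + 1) with a TPM of at least 1 in at least 2 libraries, only the 4 libraries compared, limma voom with sample weights for efficiency, and each library left out in turn. Chosen after seeing the data were removal of each library's trend with GC content (lowess, span 0.3, prior count 2), the block with that removal, and counting the young control footprint libraries as 1 sample. GC content came from an annotation of another build by gene symbol, for 95.2% of tested RNA genes and 98.2% of footprint genes.

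The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. In RNA-seq 10 and 69 of these were called, with 10 false calls among 13062 genes, and in Ribo-seq 10 and 73, with 3 false calls among 11140. For efficiency 0 and 28 were called, with 6 false calls among 11017, so edgeR at this size missed most simulated 2-fold changes. Simulated libraries were drawn independently, without the deviation that same-numbered RNA libraries share, and the fit with the block was not simulated. As a share of all calls in the simulation, false calls exceeded the adjusted p threshold in RNA-seq and efficiency but not in Ribo-seq. Genes were changed only for heat shock in young cells, so recovery of a difference of responses was not tested. Raw reads, footprint periodicity and isoforms were not analysed here.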

Results

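Transcripts and ribosome footprints were measured in WI-38 cells, a line of human lung fibroblasts that stops dividing after a limited number of passages. Young cells were at passage 24 and senescent cells at passage 36, and each was kept as control or heat shocked for 2 h at 44 °C (written 440C in the labels and read as a lost degree sign). RNA-seq measured the transcripts, and Ribo-seq, the sequencing of mRNA stretches covered by ribosomes, measured their use by ribosomes. The 16 libraries fell into 8 groups of 2. Before the experiment the cells had been starved of serum and refed. RNA-seq libraries held 26434514 to 37126871 counts and Ribo-seq libraries 4581141 to 9104077. The title and design of the series ask how heat shock and protein homeostasis differ in senescence. Changes are log2 fold changes ± SE (n = 2 libraries per group), relative to the bulk of genes. The SE was derived from the test, as the size of the change over the square root of F, and is approximate. For the heat shock gene HSPA1A in RNA it was 0.351 in young cells, 0.340 in senescent cells and 0.366 for their difference. The last value is too small for a difference of independent groups. Adjusted p values are from edgeR's quasi-likelihood test.

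The first question was which transcripts heat shock changed in young cells. Here and below the largest changes are those among called genes with a mean of at least 10 CPM, counts scaled to library size, in a group compared. Genes of cytosolic chaperones rose most. HSPA6, an inducible member of the HSP70 family, rose by 11.45 ± 0.45 (adjusted p = 5.07e-05). HSPA1B and HSPA1A, near-identical copies of the main inducible HSP70, rose by 8.24 ± 0.36 and 8.06 ± 0.35. DNAJA4 and DNAJB1, co-chaperones of HSP70, rose by 5.95 ± 0.60 and 5.74 ± 0.27. HSPA1A+HSPA1B, the sum of the copies, went from 128 ± 16.5 to 36024 ± 7400 CPM (SD, n = 2). They made up 3.31% ± 0.534 of all RNA-seq counts of heat-shocked young cells, against 0.0143% ± 0.00158 in controls.

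Of 43 measured cytosolic heat shock proteins and co-chaperones, 17 rose, 26 did not pass, and 24 were higher adjusted over the list alone. BAG3, a partner of HSP70, rose by 5.11 ± 0.24, HSPH1, an HSP110 exchange factor, by 4.36 ± 0.66, HSPB1, a small heat shock protein, by 2.43 ± 0.21, and HSPA8, the constitutive HSP70, by 1.78 ± 0.18. HSP90AA1 gave 2.20 ± 0.54 (adjusted p = 0.138; 8.67e-05 with replicate number as a block). The list passed camera (adjusted p = 6.28e-100; adjusted p = 4.01e-04 with an estimated correlation). Of 40 genes for ER chaperones and the unfolded protein response, 3 rose and 37 did not pass, with 6 higher adjusted over the list alone. They were HERPUD1 (2.71 ± 0.46), a component of ER-associated degradation, HSPA5 (1.78 ± 0.32), the ER chaperone BiP, and XBP1 (1.06 ± 0.19), a transcription factor of the unfolded protein response. The list passed camera (adjusted p = 1.21e-08), with adjusted p = 0.126 with an estimated correlation. Of 28 PERK-ATF4 targets 4 rose, with 5 higher and 1 lower adjusted over the list alone. The 4 were PPP1R15A (2.02 ± 0.25), a phosphatase subunit that acts on eIF2α, DDIT3 (2.20 ± 0.35), ATF4 (1.26 ± 0.20) and SLC3A2 (1.69 ± 0.31). For this list camera gave adjusted p = 1.10e-04, and adjusted p = 0.783 with an estimated correlation.

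UBB (1.48 ± 0.19), which codes for ubiquitin, and ZFAND2A (2.92 ± 0.32), a regulator of the proteasome, were among the 3 of 24 ubiquitin and autophagy genes that rose, with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.217 with an estimated correlation). In the extracellular matrix list 2 of 36 genes rose, the same number as adjusted over the list alone (adjusted p = 0.217 with an estimated correlation). They were SERPINH1 (2.33 ± 0.22), the collagen chaperone HSP47, and FN1 (1.67 ± 0.26), fibronectin. Of 23 p53 targets 4 fell, with 6 lower adjusted over the list alone (adjusted p = 0.0561 with an estimated correlation). They were BTG2, an antiproliferative gene (−2.75 ± 0.34), the pro-apoptotic BBC3 (−3.86 ± 0.51), SESN1 (−1.87 ± 0.30) and AEN (−1.46 ± 0.20). Among 26 immediate early genes FOS (3.91 ± 0.60), IER5 (2.66 ± 0.20) and DUSP2 (2.32 ± 0.33) rose and IER3 fell, and 5 were higher and 5 lower adjusted over the list alone. Among genes of at least 10 CPM, which BBC3 did not reach, the largest falls were IER3 (−2.90 ± 0.42), the cytokine LIF (−2.89 ± 0.34), BTG2, HPS6 (−2.58 ± 0.24) and AP5B1 (−2.40 ± 0.35). No member passed in 4 lists: ribosomal proteins (median 0.24, 79 of 79 above 0; adjusted p = 0.783 with an estimated correlation), translation factors (0.17; adjusted p = 0.783 with an estimated correlation), the chaperonin TRiC with prefoldin (0.33; adjusted p = 0.783 with an estimated correlation) and oxidative phosphorylation (0.17; adjusted p = 0.836 with an estimated correlation).

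In all, 88 transcripts rose and 62 fell of 13177 tested, and 480 rose and 676 fell with replicate number as a block, a term that same-numbered RNA libraries call for. Scaling by library size only, which shifted the median of all genes to −0.27, gave 60 higher and 134 lower, so medians of small size depend on the scaling. Without young control replicate 1 the count was 33, the lowest of 8 such fits.

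In senescent cells the same question gave many of the same genes. HSPA6 (11.37 ± 0.45), HSPA1B (7.92 ± 0.36), HSPA1A (7.34 ± 0.34), the transcription factor FOS (5.40 ± 0.65) and DNAJA4 (5.39 ± 0.63) rose most. HSPA1A+HSPA1B rose from 128 ± 29.6 to 24886 ± 6613 CPM, and made up 2.24% ± 0.417 of counts, against 0.0136% ± 0.00274 in controls. The largest falls were IER3 (−2.65 ± 0.42), the matricellular gene CYR61 (−2.28 ± 0.22), CCDC71 (−1.98 ± 0.25) and SNRNP35 (−1.84 ± 0.24), a component of the minor spliceosome.

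Of the 43 cytosolic chaperone genes 12 rose and 31 did not pass, with 20 higher adjusted over the list alone (camera adjusted p = 4.86e-69; adjusted p = 8.98e-04 with an estimated correlation). DNAJB1 (5.01 ± 0.26), BAG3 (3.74 ± 0.22), HSPB1 (1.57 ± 0.20) and HSPA8 (1.12 ± 0.18) were among them. HSPH1 gave 3.50 ± 0.63 (adjusted p = 0.0725; 3.40e-04 with the block) and HSP90AA1 1.37 ± 0.53 (adjusted p = 0.504; 0.00132 with the block). No ER chaperone passed, with HSPA5 at 0.33 ± 0.31 (adjusted p = 0.875). UBB (1.18 ± 0.19) was among the ubiquitin genes that rose of 24, with 3 higher and 1 lower adjusted over the list alone. PPP1R15A (2.62 ± 0.25) was the PERK-ATF4 target that rose of 28, with 2 higher and 2 lower adjusted over the list alone. In the immediate early list FOS, DUSP2 (4.54 ± 0.37) and IER5 (2.83 ± 0.21) rose and IER3 fell, and 6 were higher and 5 lower adjusted over the list alone (adjusted p = 0.822 with an estimated correlation). SERPINH1 (1.56 ± 0.22) and FN1 (1.84 ± 0.27) rose in the extracellular matrix list, 2 also adjusted over the list alone (adjusted p = 0.402 with an estimated correlation). No p53 target passed, with 3 lower adjusted over the list alone and a median of −0.44 (adjusted p = 0.133 with an estimated correlation). Ribosomal protein transcripts had a median of 0.28 and no member passed (adjusted p = 0.822 with an estimated correlation). Their mean log2 level was 9.42 in each senescent control, and 9.51 and 9.85 in senescent heat shock replicates 1 and 2. Most of the rise was thus in replicate 2.

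In all 48 transcripts rose and 28 fell, and 351 rose and 477 fell with the block. Library size only gave 41 higher and 53 lower, with the median of all genes at −0.23. Leaving out senescent control replicate 2 gave 15, the lowest of 8 such fits. Of the transcripts called in young cells, 45 rose and 22 fell in both, and none was called in opposite directions. If the calls were independent, 0.321 and 0.132 would be expected. Both comparisons share a spread per gene pooled over groups, so these expected values may be too low.

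Whether the transcript response differed between young and senescent cells was tested as the difference of the responses. The median difference over the 43 cytosolic chaperones was −0.53, with 36 of 43 below 0 and 2 lower adjusted over the list alone (camera adjusted p = 1.95e-17; adjusted p = 0.0131 with an estimated correlation). With replicate number as a block that call was lost (adjusted p = 0.103 with an estimated correlation), and fry gave 0.0705. BAG3 differed by −1.37 ± 0.29, HSPB1 by −0.86 ± 0.28, DNAJB1 by −0.72 ± 0.31, HSPA1A by −0.71 ± 0.37 and HSPA8 by −0.66 ± 0.25. None of these passed when adjusted over all genes. BAG3 and FKBP4 (−1.50 ± 0.27) were the 2 lower adjusted over the list alone. All 12 members called in senescent cells had a difference below 0, from −1.50 to −0.07. The list's median was −0.29 without young heat shock replicate 1, the value nearest to 0 of 8 such fits. ER chaperones had a median difference of −0.28 (34 of 40 below 0; camera adjusted p = 4.43e-12; adjusted p = 0.0943 with an estimated correlation), with HSPA5 at −1.45 ± 0.44.

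Of 13177 transcripts 0 passed by edgeR, against 119 at an unadjusted p under 0.05, 3 by DESeq2 and 2 by limma on TPM. With replicate number as a block 1 gene passed. Fry gave adjusted p = 0.225 for ER chaperones.

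**Figure D1:**
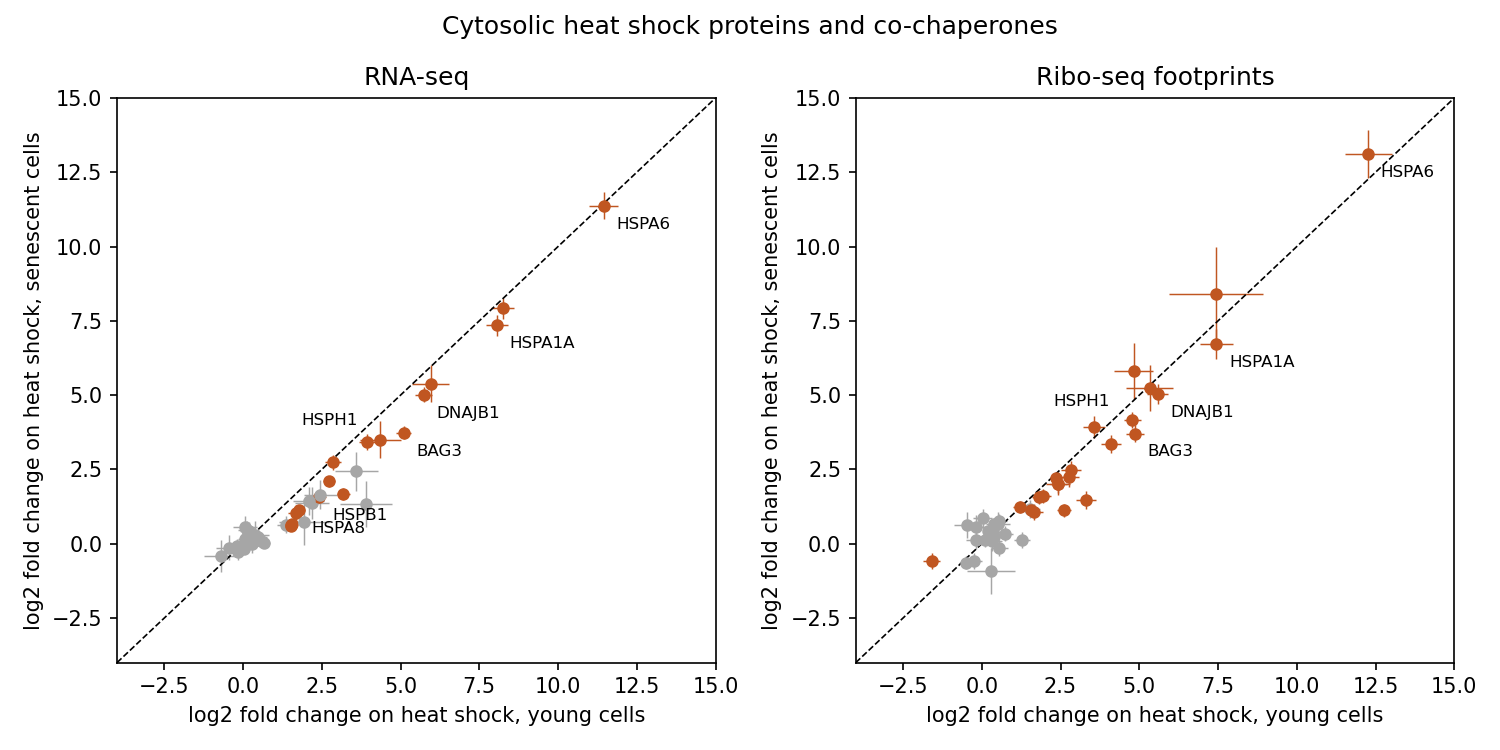
Log2 fold change on heat shock of each cytosolic heat shock protein or co-chaperone in young (x axis) and senescent cells (y axis), in RNA-seq (left) and Ribo-seq (right). Points are genes, bars are ± 1 SE, orange marks genes called in either state, grey the others, and the dashed line is equality; 36 of the 43 genes in RNA-seq lie below it, with a median difference of −0.53.

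Senescent and young control cells were compared for their transcripts at rest. CCND2, which codes for cyclin D2, was higher in senescent cells by 3.07 ± 0.35, ADAMTS19, a secreted metalloproteinase, by 2.99 ± 0.34, and FIBIN by 2.82 ± 0.30. EGFLAM, a matrix protein, was lower by −4.08 ± 0.45, a gene named outside the rule because few passed. BOLA2B was also called, but both young control libraries were at 0 counts and the gene has a near-identical copy, so no fold is given. CDKN1A, the cell cycle inhibitor p21, gave 0.95 ± 0.28 (adjusted p = 0.432; 0.0148 with the block), CDKN2A 0.28 ± 0.29, LMNB1, a lamin known to be lost in senescence, −1.23 ± 0.49 and MKI67, a proliferation marker, −1.18 ± 0.73.

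No member passed in any list described here. All 45 cell cycle genes were below 0 (median −0.75; camera adjusted p = 2.53e-11; adjusted p = 0.620 with an estimated correlation), and 8 fell with the block. Interferon-stimulated genes had a median of 0.71, with 19 of 22 above 0 (adjusted p = 0.590 with an estimated correlation). Senescent control replicate 2 stood apart, with a mean log2 level of 3.33 against 2.51 in replicate 1 and 2.27 and 2.45 in young controls. The secretory phenotype (median 0.13, 2 higher adjusted over the list alone), oxidative stress (0.28, 2 higher adjusted over the list alone) and extracellular matrix lists (−0.19, 5 lower adjusted over the list alone) each gave adjusted p = 0.522 with an estimated correlation. P53 targets (0.27) and ubiquitin genes (0.22) also gave adjusted p = 0.522 with an estimated correlation. PERK-ATF4 targets (0.26) and SR proteins (−0.16) gave adjusted p = 0.688 with an estimated correlation, and oxidative phosphorylation (0.10) gave 0.782. The mean log2 levels of PERK-ATF4 targets were 5.64 and 6.10 in senescent controls and 5.47 and 5.83 in young controls. Libraries of the same group thus differed by more than the 2 states did, with replicate 2 the higher in both. Within each replicate number the senescent control lay above the young control. Part of the gap between replicates may thus be the deviation that same-numbered RNA libraries share. Of the markers of other cell types, 6 of 7 epithelial markers (median 0.45; adjusted p = 0.522 with an estimated correlation) and 3 of 5 endothelial markers (0.61, 1 higher adjusted over the list alone; adjusted p = 0.676 with an estimated correlation) were above 0. KRT19, a keratin of simple epithelia, gave 0.87 ± 0.25.

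In all 4 transcripts were higher and 1 lower, and 283 and 207 with the block. Scaling by library size and each of the 8 fits with a library left out called 0, against 949 at an unadjusted p under 0.05 and 144 by DESeq2, and changes correlated with GC content across genes (Spearman 0.419; genes are not independent replicates).

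Senescent and young cells were also compared for their transcripts under heat shock. Of the 43 cytosolic chaperones 36 were below 0 (median −0.41), none passed, and 5 were lower adjusted over the list alone (adjusted p = 0.0797 with an estimated correlation). HSPA5 gave −1.12 ± 0.31 and HSPA1A −0.67 ± 0.26, with adjusted p of 0.00615 and 0.0133 in the fit with the block. CDKN1A gave 1.25 ± 0.29 (0.00606 with the block), LMNB1 −0.73 ± 0.49, CDKN2A 0.17 ± 0.29 and MKI67 −0.24 ± 0.72. Other lists that passed camera, each without a member past the test, lost the call with an estimated correlation. They were ER chaperones (median −0.27), the secretory phenotype (0.09), the extracellular matrix (−0.23), oxidative stress (0.22) and epithelial markers (0.40), each with adjusted p = 0.447 with an estimated correlation, and p53 targets (0.32) with 0.193. SR proteins (−0.38) gave adjusted p = 0.573 with an estimated correlation, immediate early (0.31) and interferon-stimulated genes (0.49) 0.790, proteasome subunits (−0.24) and TRiC (−0.29) 0.909, and cell cycle genes (−0.21) 0.987. Adjusted over the list alone, 6 secretory genes, 2 p53 targets, 3 oxidative stress genes, 1 immediate early gene and 1 epithelial marker were higher, and 1 secretory and 7 matrix genes lower. By edgeR 0 transcripts passed, against 1520 at an unadjusted p under 0.05, 245 by DESeq2 and 6 by limma on TPM, while the fit with the block gave 1070 higher and 741 lower. Changes correlated with GC content across genes (Spearman 0.486).

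Footprint counts per gene, which follow transcript level as well as ribosomes per mRNA, were compared for heat shock in young cells. Most of the largest rises were of chaperone mRNAs. HSPA6 rose from 0.675 ± 0.817 to 3230 ± 1298 CPM (SD, n = 2), HSPA1A by 7.45 ± 0.52, DNAJB1 by 5.58 ± 0.34, HSPA1L, another HSP70, by 5.33 ± 0.74, and ZFAND2A, the regulator of the proteasome, by 5.58 ± 0.47. PABPC1, the main poly(A)-binding protein, fell most, by −4.06 ± 0.42. CAMK2N1 (−3.52 ± 0.44), CCNI, which codes for cyclin I (−3.27 ± 0.38), SBF1 (−2.78 ± 0.39) and ELMSAN1 (−2.61 ± 0.37) followed.

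Of 43 cytosolic chaperones 21 rose and BAG1 fell (−1.59 ± 0.28), with 25 higher and 1 lower adjusted over the list alone (adjusted p = 0.00197 with an estimated correlation). HSPH1 rose by 4.78 ± 0.27, BAG3 by 4.86 ± 0.29, HSP90AA1 by 2.76 ± 0.33, HSPB1 by 2.42 ± 0.38 and HSPA8 by 1.95 ± 0.24. XBP1 (2.30 ± 0.21), HERPUD1 (2.60 ± 0.37) and HSPA5 (1.71 ± 0.20) were the 3 of 39 ER genes that rose, with 9 higher adjusted over the list alone (adjusted p = 0.180 with an estimated correlation). ATF4 (3.23 ± 0.33), DDIT3 (2.96 ± 0.39), PPP1R15A (2.84 ± 0.44) and SLC3A2 (1.63 ± 0.27) were the 4 of 28 PERK-ATF4 targets that rose, with 5 higher adjusted over the list alone (adjusted p = 0.370 with an estimated correlation). The ferritin subunits FTH1 (2.43 ± 0.18) and FTL (2.48 ± 0.24), which store iron, rose in the oxidative stress list, with 6 of 23 higher adjusted over the list alone (adjusted p = 0.0793 with an estimated correlation). CLK4 (3.41 ± 0.44) and CLK1 (3.34 ± 0.53), kinases of SR proteins, rose with SF3B1 (1.05 ± 0.17) and SRSF11 (1.03 ± 0.18) among 29 splicing genes, with 10 higher and 1 lower adjusted over the list alone (adjusted p = 0.180 with an estimated correlation). HSPD1, the mitochondrial HSP60, rose by 2.08 ± 0.40, of 16 mitochondrial chaperones and proteases, 2 of them higher adjusted over the list alone. COL1A1, the main chain of type I collagen, fell by −2.08 ± 0.22, while SERPINH1 (2.02 ± 0.18) and FN1 (1.42 ± 0.24) rose, with 4 of 36 matrix genes higher and 2 lower adjusted over the list alone (adjusted p = 0.180 with an estimated correlation).

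IER5 (2.78 ± 0.25) rose and SRF, KLF2 and RHOB fell (−1.32 ± 0.23, −1.97 ± 0.35 and −1.03 ± 0.20) among 23 immediate early genes, with 5 higher and 4 lower adjusted over the list alone. SESN1 fell (−2.06 ± 0.34) among 23 p53 targets, with 2 lower adjusted over the list alone, and ZFAND2A rose among 24 ubiquitin genes, with 4 higher and 2 lower adjusted over the list alone (both adjusted p = 0.180 with an estimated correlation). In translation factors (median 0.25), PABPC1 fell, with 1 higher and 2 lower adjusted over the list alone (adjusted p = 0.699 with an estimated correlation). No member passed among TRiC (0.48) and oxidative phosphorylation (0.32; both adjusted p = 0.370 with an estimated correlation), proteasome subunits (0.26; adjusted p = 0.483 with an estimated correlation), ribosomal proteins (−0.21; adjusted p = 0.480 with an estimated correlation) and cell cycle genes (−0.36; adjusted p = 0.765 with an estimated correlation). In all 87 genes rose and 43 fell of 11288, 173 rose and 157 fell with replicate number as a block, and 68 rose and 169 fell by library size only, which put the median of all genes at −0.28. The young control libraries were nearly alike (chi-square per degree of freedom 1.65, against 14.8 to 31.2 in the other footprint groups). Whether they are independent samples is not given in the sources used here, and the main fits treat them as such. If they are not, the spread pooled over groups is too small, and so are p values of footprints and efficiency. Counted as 1 sample, or with either left out, they left fewer calls.

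In senescent cells heat shock was tested on footprints in the same way, and 943 genes passed against 130 in young cells. That order turned in fits of only the 4 libraries compared (270 against 362) and without senescent heat shock replicate 2 (237 against 275), and the test of the difference itself called 0 genes by edgeR. HSPA6 went from 0.357 ± 0.211 to 3488 ± 1247 CPM and HSPA1A rose by 6.73 ± 0.50. HSPA1A+HSPA1B rose by 7.38 ± 0.32, against 7.45 ± 0.32 in young cells. FOS went from 0.338 ± 0.478 to 58.9 ± 58.7 CPM. PABPC1 (−5.16 ± 0.45), PPP1R12C, a subunit of a myosin phosphatase (−4.18 ± 0.43), CAMK2N1 (−4.05 ± 0.45) and COL1A1 (−3.83 ± 0.24) fell most. TICAM2 and BIVM-ERCC5 were also named by the rule, but they belong to loci with read-through transcripts and had 0 footprint counts in senescent control and in senescent heat shock libraries respectively, so no fold is given.

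Of 43 cytosolic chaperones 22 rose, with 27 higher and 1 lower adjusted over the list alone (adjusted p = 0.00661 with an estimated correlation). DNAJB1 rose by 5.04 ± 0.34, HSPH1 by 4.15 ± 0.27, BAG3 by 3.71 ± 0.28, HSP90AA1 by 2.24 ± 0.33, HSPB1 by 2.03 ± 0.38 and HSPA8 by 1.61 ± 0.23. In the extracellular matrix list footprints of COL1A1, COL1A2 (−2.03 ± 0.21), COL3A1 (−1.76 ± 0.17), COL5A1 and COL4A1 fell, while SERPINH1 (1.49 ± 0.17), FN1 and TNC rose. That made 3 higher and 5 lower of 36 matrix genes, with 8 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.930). In the fibroblast marker list COL1A1, COL1A2 and COL3A1 were the 3 of 11 that fell, with 2 higher and 4 lower adjusted over the list alone. That list's median was 0.23 while camera's direction was down (adjusted p = 0.205 with an estimated correlation). Of 78 ribosomal protein mRNAs 10 fell, and 28 were lower adjusted over the list alone (median −0.52; camera adjusted p = 3.11e-09; adjusted p = 0.257 with an estimated correlation). RPS20 fell by −2.02 ± 0.30, RPS27 by −1.41 ± 0.23, RPL13A by −1.38 ± 0.22 and RPL27A by −1.19 ± 0.22. Of 29 splicing genes 12 rose, and 16 were higher adjusted over the list alone (adjusted p = 0.205 with an estimated correlation), with CLK4 at 4.30 ± 0.48, CLK1 at 3.93 ± 0.56, SF3B1 at 1.40 ± 0.17 and SON at 1.25 ± 0.20. PABPC4 (−3.61 ± 0.47) and TPT1 (−1.40 ± 0.32) also fell among 41 translation factors, and EIF5A (1.04 ± 0.19) and EIF4G2 (1.05 ± 0.21) rose, with 8 higher and 3 lower adjusted over the list alone.

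PPP1R15A (4.06 ± 0.46), ATF4 (3.76 ± 0.34), DDIT3 (2.60 ± 0.40) and SLC3A2 (1.44 ± 0.27) rose among PERK-ATF4 targets and SESN2 and SLC7A11 (−1.28 ± 0.26), a cystine transporter, fell, with 5 higher and 4 lower adjusted over the list alone (adjusted p = 0.666 with an estimated correlation). XBP1 (2.16 ± 0.21), HERPUD1 and HSPA5 (1.14 ± 0.20) rose and DNAJC10 (−1.39 ± 0.30) and SYVN1 (−0.78 ± 0.20), a ubiquitin ligase of ER-associated degradation, fell among 39 ER genes, with 3 higher and 2 lower adjusted over the list alone (adjusted p = 0.564 with an estimated correlation). FTH1 (2.55 ± 0.18), FTL (2.05 ± 0.24), HMOX1 (1.43 ± 0.35), which degrades heme, CAT and SOD1 rose and SLC7A11 fell among 23 oxidative stress genes, with 10 higher and 1 lower adjusted over the list alone (adjusted p = 0.205 with an estimated correlation). ZFAND2A (4.57 ± 0.47), UBB (1.89 ± 0.38) and VCP were among the ubiquitin genes that rose and ULK1 (−1.93 ± 0.37), a kinase that starts autophagy, fell of 24, with 10 higher and 3 lower adjusted over the list alone (adjusted p = 0.205 with an estimated correlation). PFDN6, CCT2 and PFDN2 rose among 14 TRiC and prefoldin genes, with 6 higher adjusted over the list alone (adjusted p = 0.283 with an estimated correlation). The list of oxidative phosphorylation had SDHB (1.07 ± 0.20) and UQCRQ (0.85 ± 0.21) higher and 12 higher adjusted over the list alone (adjusted p = 0.283 with an estimated correlation). GRPEL1 (0.88 ± 0.20) and HSPE1 (0.89 ± 0.22) rose among 16 mitochondrial chaperones and proteases, both also adjusted over the list alone. PSMD1 (0.87 ± 0.19) rose among 31 proteasome subunits, all 31 above 0, with 1 higher adjusted over the list alone (adjusted p = 0.307 with an estimated correlation).

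CDKN2C, an inhibitor of cyclin-dependent kinases, rose among 13 senescence genes, from 7 counts over both control libraries to 259, with 1 higher adjusted over the list alone (adjusted p = 0.564 with an estimated correlation). IER5 (3.42 ± 0.26), FOS, FOSB, DUSP1 and DUSP2 (from 0 counts over both control libraries to 51) rose and SRF (−1.77 ± 0.24), KLF2 (−2.18 ± 0.36) and RHOB fell among immediate early genes, with 7 higher and 4 lower adjusted over the list alone. RRM1 (1.19 ± 0.26), a subunit of ribonucleotide reductase, rose among 45 cell cycle genes, 40 of them above 0 (adjusted p = 0.760 with an estimated correlation). In all 352 genes rose and 591 fell, 675 rose and 992 fell with the block, and 173 rose and 1180 fell by library size only, with the median of all genes at −0.25. With the young control footprint libraries as 1 sample 100 rose and 147 fell, and leaving out 1 library gave 237 (without senescent heat shock replicate 2) to 1934 calls (without senescent heat shock replicate 1).

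The difference of the footprint responses asked whether the change of footprints on heat shock differed between the states. Cytosolic chaperones had a median difference of −0.23, with 26 of 43 below 0 (camera adjusted p = 0.0608; adjusted p = 0.691 with an estimated correlation), which does not establish a difference. With replicate number as a block camera at the preset correlation gave adjusted p = 0.0262. BAG3 gave −1.15 ± 0.35, HSPA1A −0.72 ± 0.56, HSPH1 −0.63 ± 0.33 and HSPA5 −0.57 ± 0.28, and HSPA1A+HSPA1B −0.07 ± 0.34. ER chaperones had a median of −0.14 with 28 of 39 below 0 (camera adjusted p = 0.0167). That call ended with an estimated correlation (adjusted p = 0.691 with an estimated correlation) and without young heat shock replicate 1 (adjusted p = 0.421), senescent heat shock replicate 1 (0.0789) or senescent control replicate 2 (0.0697). By edgeR 0 genes passed, against 554 at an unadjusted p under 0.05 and 10 by DESeq2.

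Footprints of senescent and young cells were also compared directly. In controls the 45 cell cycle mRNAs were all below 0 (median −1.16; camera adjusted p = 1.18e-18; adjusted p = 0.683 with an estimated correlation). The median was −0.74 without senescent control replicate 1 and −1.72 without replicate 2. MKI67 gave −1.56 ± 0.65, LMNB1 −1.54 ± 0.51, CDKN1A 0.65 ± 0.29 and CDKN2A 0.20 ± 0.35, none of them past the test. Other lists above or below the bulk were the senescence genes (median −0.48), the secretory phenotype (0.23, 4 higher adjusted over the list alone) and interferon-stimulated genes (0.59), each with adjusted p = 0.683 with an estimated correlation. The interferon-stimulated genes had mean log2 levels of 3.31 and 4.28 in senescent controls (replicates 1 and 2) and 3.27 in each young control. Of the endothelial markers 2 were measured, too few for a list test, and both were above 0 (median 1.28). P53 targets (0.33) gave adjusted p = 0.283 with an estimated correlation and oxidative stress genes (0.29, 2 higher adjusted over the list alone) gave 0.20. By edgeR 0 genes passed, against 885 at an unadjusted p under 0.05 and 120 by DESeq2, and with replicate number as a block 17 were higher and 10 lower.

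Under heat shock ELN, elastin, was lower in senescent cells by −2.36 ± 0.24 (adjusted p = 0.0492), at 23.6 ± 0.923 against 121 ± 25.3 CPM. It was the matrix gene past the test, with 1 higher and 9 lower adjusted over the list alone (adjusted p = 0.262 with an estimated correlation). CDKN1A gave 1.17 ± 0.29, CDKN2A −0.14 ± 0.35, LMNB1 −0.61 ± 0.50 and MKI67 0.28 ± 0.63. Ribosomal proteins (median −0.36) and epithelial markers (0.55, 4 of 4 above 0) gave adjusted p = 0.350 with an estimated correlation, and proteasome subunits (0.20) and oxidative phosphorylation (0.19) gave 0.536. Oxidative stress (0.34) and p53 targets (0.31) gave adjusted p = 0.259 with an estimated correlation, fibroblast markers (−0.14) 0.262, interferon-stimulated genes (1.04) 0.445 and the secretory phenotype (0.27) 0.472. Adjusted over the list alone, 2 oxidative stress, 2 interferon-stimulated and 2 secretory genes and 1 epithelial marker were higher, and 4 fibroblast markers lower. The interferon-stimulated genes had mean log2 levels of 3.41 and 4.44 in senescent heat shock replicates 1 and 2, against 3.04 and 3.20 in young cells, so replicate 2 stood apart. ELN was the only gene called by edgeR, against 1463 at an unadjusted p under 0.05 and 143 by DESeq2, and with the block 8 were higher and 10 lower. Its call ended with relative log expression scaling, with the young control libraries as 1 sample and without any of 6 of the 8 libraries, while 494 genes passed without senescent heat shock replicate 1.

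**Figure D2:**
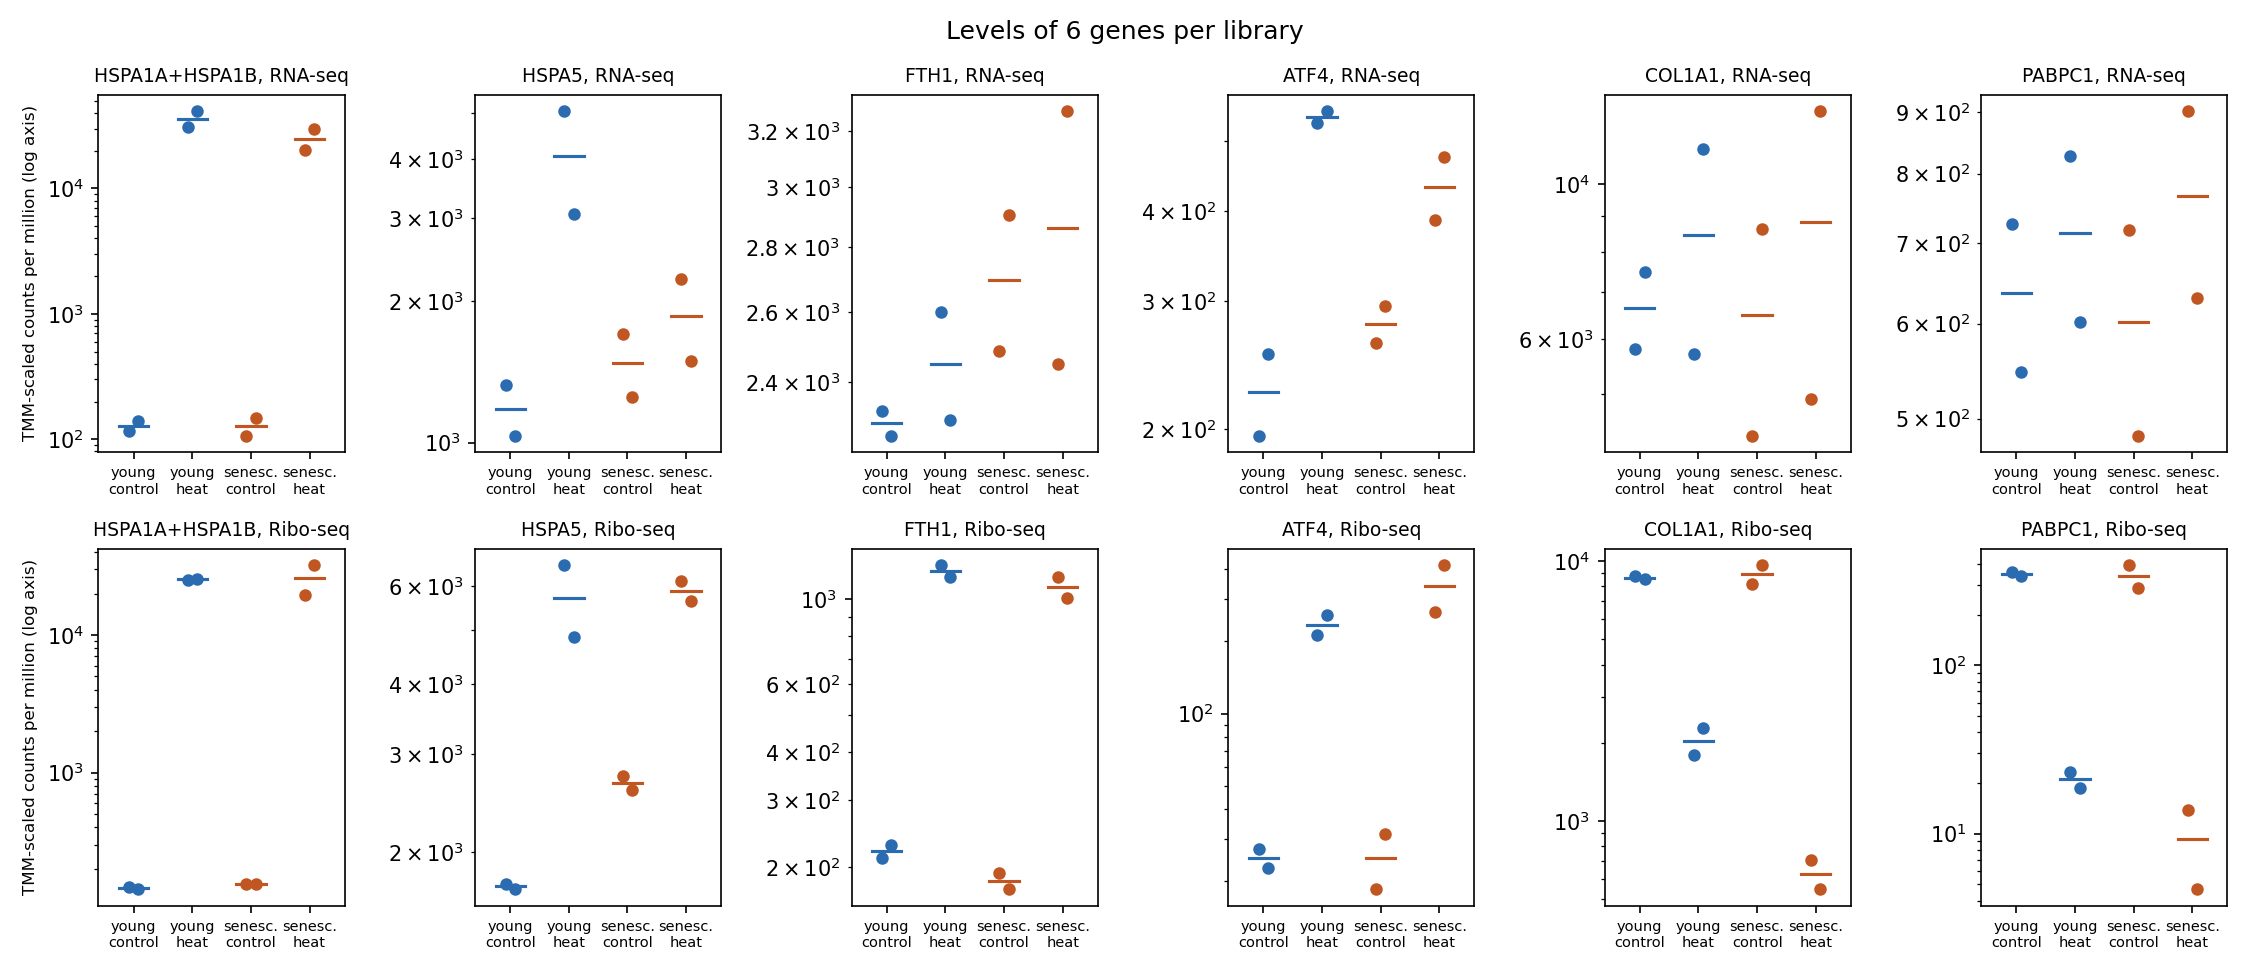
Scaled CPM (log axes, which differ between panels) of 6 genes in RNA-seq (top) and Ribo-seq (bottom). Points are the 2 libraries of a group and lines their mean, with young cells in blue and senescent cells in orange; COL1A1 footprints fell to 2042 and 627 CPM on heat shock, with RNA at 8457 and 8819.

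Translational efficiency, the change of footprints beyond that of RNA, was tested for heat shock in young cells over 11166 genes. FTH1 (2.33 ± 0.26) and FTL (2.25 ± 0.30), the ferritin mRNAs, rose. EPAS1, which codes for the transcription factor HIF-2α, rose by 2.78 ± 0.38, and ATF5, a transcription factor of the stress response, by 3.40 ± 0.55, from 9 footprint counts over both controls. PABPC1 (−4.22 ± 0.53), CCNI (−3.57 ± 0.48), DLG4 (−3.48 ± 0.59) and CAMK2N1 (−3.38 ± 0.43) fell. BOLA2B and NEDD8-MDP1, a read-through transcript, were also called, but with 0 counts in 1 of the groups compared, so no fold is given.

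The oxidative stress list, in which FTH1 and FTL rose of 20 genes and 3 were higher adjusted over the list alone, held its call (camera adjusted p = 6.02e-10; adjusted p = 0.00271 with an estimated correlation). Ribosomal proteins had a median of −0.45 with 77 of 78 below 0, and no member passed (camera adjusted p = 4.90e-20; adjusted p = 0.286 with an estimated correlation). Splicing genes (median 0.36; adjusted p = 0.483 with an estimated correlation), proteasome subunits (0.15; adjusted p = 0.722 with an estimated correlation) and fibroblast markers (−0.11, 2 lower adjusted over the list alone; adjusted p = 0.298 with an estimated correlation) had no member past the test. Cytosolic chaperones had a median of −0.01 and did not pass (camera adjusted p = 0.959), with HSPA1A at −0.61 ± 0.51, BAG3 at −0.25 ± 0.33, HSPA8 at 0.17 ± 0.29 and HSPA5 at −0.07 ± 0.38. In all 4 genes rose and 6 fell, 14 rose and 43 fell with replicate number as a block, and 5 were called with the young control footprint libraries as 1 sample.

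In senescent cells 26 genes rose and 245 fell in efficiency, a split that became 322 and 834 with replicate number as a block and 127 and 161 without footprint library senescent control replicate 2. ATF5 (3.50 ± 0.52), CDKN2C (3.49 ± 0.64), ATF4 (3.11 ± 0.38), ZFAND2A (3.06 ± 0.58) and EPAS1 (2.78 ± 0.38) rose. Of these, ATF5 and CDKN2C rose from only 10 and 7 footprint counts over both senescent control libraries. PABPC1 (−5.52 ± 0.55), PPP1R12C (−4.38 ± 0.46), COL1A1 (−4.29 ± 0.61), COL5A1 (−3.31 ± 0.51), COL1A2 (−2.55 ± 0.34) and COL3A1 (−2.25 ± 0.46) fell. COL1A1 footprints went from 8902 ± 1086 to 627 ± 113 CPM, with RNA at 6491 ± 3010 and 8819 ± 5514. GLIS2, a zinc finger factor, fell to 1 footprint count over both libraries, and TICAM2, TVP23C and BIVM-ERCC5 rest on groups of 0 to 2 counts, so their folds are not given.

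Of 78 ribosomal protein mRNAs 9 fell and 34 were lower adjusted over the list alone (median −0.80, 77 of 78 below 0; camera adjusted p = 5.48e-21; adjusted p = 0.248 with an estimated correlation). RPS20 fell by −2.26 ± 0.38, RPL13A by −1.84 ± 0.34, RPS27 by −1.72 ± 0.29 and RPS19 by −1.37 ± 0.28. PABPC4 (−3.75 ± 0.51) and TPT1 (−1.61 ± 0.39), a growth-related protein, fell with PABPC1 among 41 translation factors, with 1 higher and 4 lower adjusted over the list alone. In the matrix list 5 of 36 fell and 6 were lower adjusted over the list alone (adjusted p = 0.403 with an estimated correlation), and 3 of 11 fibroblast markers, COL1A1, COL1A2 and COL3A1, fell, with 4 lower adjusted over the list alone (adjusted p = 0.248 with an estimated correlation). The median of the fibroblast markers was 0.24 while camera's direction was down. FTH1 (2.44 ± 0.26) and FTL (1.63 ± 0.30) rose of 20 oxidative stress genes, with 4 higher adjusted over the list alone (camera adjusted p = 1.93e-05; adjusted p = 0.0241 with an estimated correlation). SON (1.40 ± 0.29) and SRSF7 (1.15 ± 0.28) rose among 29 splicing genes, with 12 higher adjusted over the list alone, and proteasome subunits had a median of 0.59 with 30 of 31 above 0 and no call (both adjusted p = 0.248 with an estimated correlation). ZFAND2A was the ubiquitin gene that rose, with 1 adjusted over the list alone (adjusted p = 0.248 with an estimated correlation). SDHB (1.08 ± 0.26) rose among 44 oxidative phosphorylation genes, with 1 adjusted over the list alone (adjusted p = 0.364 with an estimated correlation). TRiC (median 0.58, 1 higher adjusted over the list alone; adjusted p = 0.403 with an estimated correlation) and cell cycle genes (0.55; adjusted p = 0.768 with an estimated correlation) had no call over all genes. XBP1 (1.66 ± 0.27) and ATF4 rose among ER and PERK-ATF4 genes, whose lists did not pass camera (adjusted p = 0.139 and 0.0546).

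The genes that fell were GC-rich, with a median of 59.6% against 49.2% over all genes. With the young control footprint libraries as 1 sample 18 rose and 128 fell, and leaving out 1 library gave 49 (without footprint library senescent heat shock replicate 2) to 668 calls (without senescent heat shock replicate 1).

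**Figure D3:**
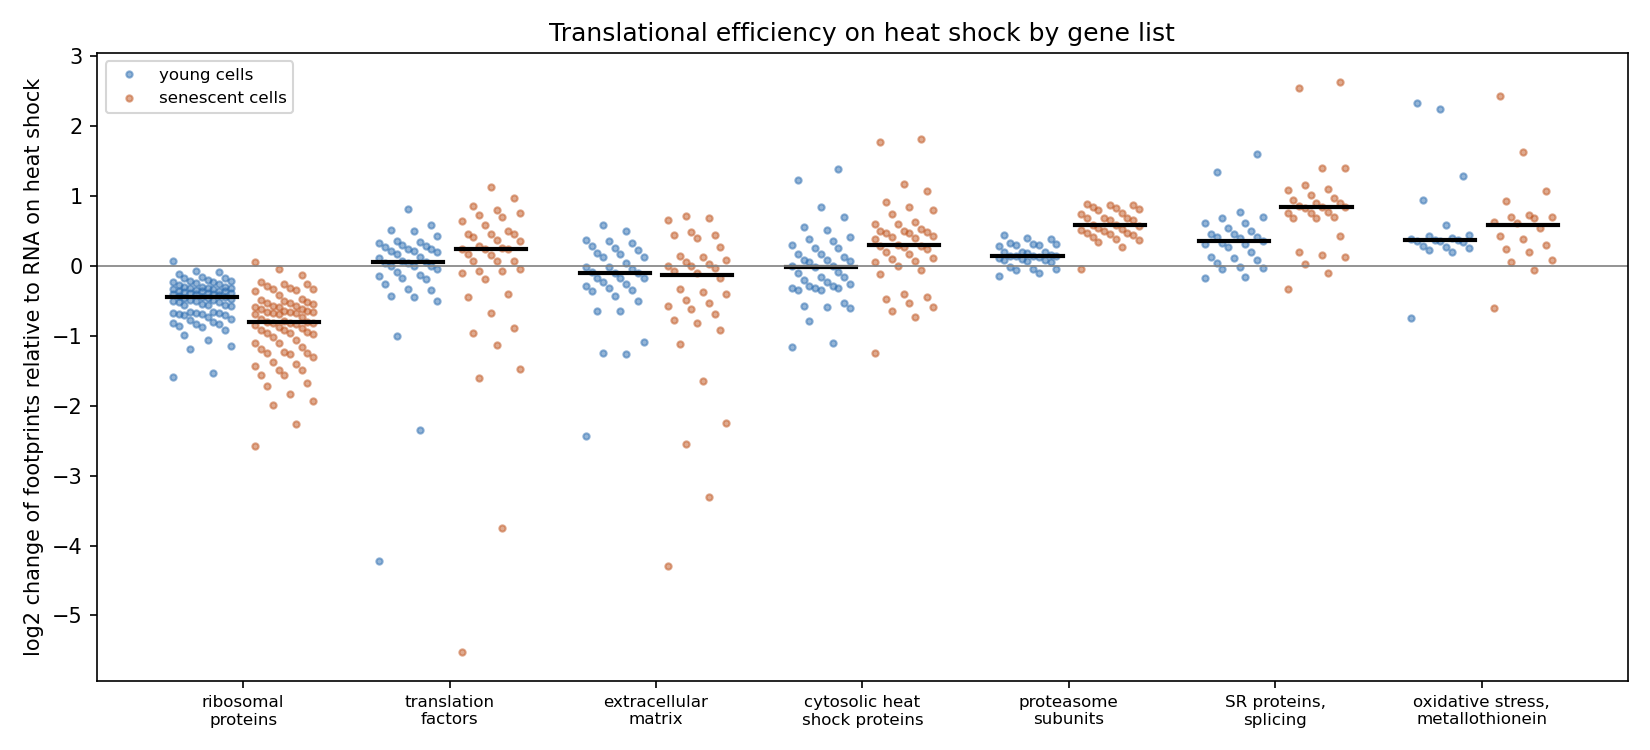
Log2 change of footprints relative to RNA on heat shock (y axis) for the genes of 7 lists (x axis), young cells in blue and senescent cells in orange. Points are genes and black lines list medians; ribosomal proteins had medians of −0.45 in young and −0.80 in senescent cells (−0.58 without RNA senescent heat shock replicate 2).

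The difference of efficiency responses between senescent and young cells was tested for the same genes. Cytosolic chaperones had a median of 0.33 (33 of 43 above 0; camera adjusted p = 0.0157; adjusted p = 0.528 with an estimated correlation), proteasome subunits 0.51 and ribosomal proteins −0.40 (adjusted p = 0.595 and 0.643 with an estimated correlation). The median was 0.29 for proteasome subunits without RNA senescent control replicate 1, and −0.17 for ribosomal proteins without footprint library senescent heat shock replicate 2. COL1A1 gave −1.86 ± 0.83, HSPA5 0.86 ± 0.54 and BAG3 0.20 ± 0.46, and none passed. BOLA2B was the only gene called, on 0 RNA counts in young controls, with 255 genes at an unadjusted p under 0.05, 4 called by DESeq2 and 0 by limma voom. That call ended with replicate number as a block, with the young control footprint libraries as 1 sample and without any of 12 of the 16 libraries. In control cells BOLA2B was also the only call for senescent against young efficiency, with 88 at an unadjusted p under 0.05, 6 by DESeq2 and 2 by limma voom. Matrix genes had a median of 0.30 (31 of 36 above 0), cell cycle genes −0.35 and oxidative phosphorylation −0.15, each with adjusted p = 0.849 with an estimated correlation and no member past the test. CDKN1A gave −0.30 ± 0.43, LMNB1 −0.32 ± 0.75, CDKN2A −0.09 ± 0.47 and MKI67 −0.39 ± 1.06.

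Lists without a camera call in the heat shock comparisons of RNA were few in members past the test. Cholesterol synthesis genes (22 measured) had medians of 0.09 in young and 0.04 in senescent cells, and contractile genes (14 measured) of 0.03 and 0.06, with CYR61 lower in both (−1.28 ± 0.21 in young cells). Mitochondrial chaperones and proteases had medians of 0.02 and −0.00, with HSPD1 at 2.09 ± 0.54 (adjusted p = 0.164; 4.34e-04 with the block) and 0.85 ± 0.53. Proteasome subunits had medians of 0.11 and −0.10. Of 11 blood cell markers 2 were measurable in RNA-seq and 1 in Ribo-seq, too few for a list test. None of the 13 mitochondrially encoded mRNAs was in the tables, so that list gave no value.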

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

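Chosen before the result was seen were camera with an estimated correlation in the main fit, the 3 scalings and the fits with 1 library left out. So was the test of GC content as the whole cause of the shared deviations of RNA libraries. The other tests given here, and the use of the scalings to test an explanation, were chosen only after the result was seen. The list results and BOLA2B below are differences between the heat shock responses of senescent and young cells, found by a test of the difference itself. The shared deviations and the fall of efficiency in senescent cells, given last, are not such differences.

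Transcripts of the 43 cytosolic chaperones differed by a median of −0.53, from −0.61 to −0.29 with 1 RNA library left out (−0.29 without young heat shock replicate 1). The 12 members called in senescent cells differed by −0.64. With the GC trend removed in the fit with the block the median of the 43 was −0.47, which argues against GC content, and the value nearest to 0 over 3 scalings was −0.46, which argues against a few abundant transcripts having moved the scaling. The 43 had a median of −0.41 for senescent against young cells under heat shock and 0.04 in controls, which argues against a higher starting level. A weaker transcript response in senescent cells is a hypothesis consistent with these values, found and tested on the same data. With the block and the GC removal the list gave adjusted p = 0.0714 with an estimated correlation. In footprints 26 of the 43 were below 0 (median −0.23). Of the 22 members called higher in footprints in either state, 17 were below 0 (median −0.41). In RNA all 17 such members were below 0 (median −0.71). The 17 in RNA are those called in young cells, whose response is subtracted, so this choice favours differences below 0. The 22 in footprints are those called in senescent cells, so the counts cannot be compared. Whether transcripts and footprints differ here is not established, since the list's difference of efficiency lost its camera call with an estimated correlation.

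In RNA, the other lists that differed were TRiC and prefoldin (−0.34; adjusted p = 0.658 with an estimated correlation), ER chaperones (−0.28; 0.0943) and PERK-ATF4 targets (−0.34; 0.658). Proteasome subunits differed by −0.18 (adjusted p = 0.737 with an estimated correlation), ubiquitin genes by −0.15 (0.348), oxidative phosphorylation by −0.11 (0.917), SR proteins by −0.24 (0.737), cell cycle genes by 0.57 (0.737), p53 targets by 0.090 (0.348) and immediate early genes by 0.22 (0.658). These medians rest in part on single libraries. Without senescent heat shock replicate 2 cell cycle genes gave −0.51 and immediate early genes 0.06. Without senescent heat shock replicate 1 PERK-ATF4 targets and proteasome subunits gave −0.06, oxidative phosphorylation 0.04, p53 targets 0.00 and ER chaperones −0.22. Without senescent control replicate 1 TRiC gave −0.12 and SR proteins 0.03, and ubiquitin genes lay between −0.24 and −0.16 in all 8 such fits.

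In footprints, ER chaperones differed by −0.14, proteasome subunits by 0.26, ribosomal proteins by −0.35, oxidative phosphorylation by 0.21, cell cycle genes by 1.21, senescence genes by 0.49, the extracellular matrix by −0.28 and splicing genes by 0.25, each with adjusted p = 0.691 with an estimated correlation. Immediate early genes differed by 0.34 (adjusted p = 0.733 with an estimated correlation). Without senescent heat shock replicate 2 the medians were 0.16 for cell cycle genes, 0.01 for senescence genes, −0.22 for ribosomal proteins, 0.06 for oxidative phosphorylation, 0.14 for proteasome subunits, 0.13 for splicing genes and −0.12 for immediate early genes. Without senescent control replicate 1 the matrix gave −0.06, and without young heat shock replicate 1 ER chaperones gave −0.09. In efficiency, cytosolic chaperones differed by 0.33 and ubiquitin genes by 0.32 (both adjusted p = 0.528 with an estimated correlation), TRiC by 0.42, proteasome subunits by 0.51 and splicing genes by 0.44 (each 0.595). Ribosomal proteins differed by −0.40 and oxidative phosphorylation by 0.31 (both adjusted p = 0.643 with an estimated correlation), cell cycle genes by 0.69 (0.771) and the extracellular matrix by −0.24 (0.753). Without footprint library senescent heat shock replicate 2 ribosomal proteins gave −0.17, ubiquitin genes 0.18 and cell cycle genes −0.29, and without footprint library senescent control replicate 1 the matrix gave −0.02. Without RNA senescent control replicate 1 cytosolic chaperones gave 0.18, TRiC 0.19, proteasome subunits 0.29 and splicing genes 0.15, and without RNA senescent heat shock replicate 1 oxidative phosphorylation gave 0.13. BOLA2B differed by 7.71, a fitted value that rests on 0 RNA counts in young controls, depends on the prior count and is no bound.

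Same-numbered RNA libraries deviated together. The deviation followed GC content, with Spearman correlations across genes from −0.64 to −0.53 in the 4 groups (the smallest −0.527), so GC content is a candidate for part of the cause. With the GC trend removed the lowest of the 6 correlations between groups was 0.336, which argues against GC content as the whole cause. For transcript length the smallest of the 4 was −0.0130, in senescent control, which argues against length as a cause shared by all 4 groups. The others were 0.129 in young control, 0.105 in young heat shock and 0.215 in senescent heat shock, so a small part there stays open. What else same-numbered libraries share was not tested, and no biological explanation was tested.

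Footprints fell against RNA in 245 genes of heat-shocked senescent cells, which had a median GC content of 59.6%. With the GC trend removed 88.2% of them were called lower, and in the fit with the block, which by itself calls more genes, 97.6%. In that fit their median moved from −2.26 to −2.06, so the removed trend made up little of the size of their fall. The genes were picked by that fall, so these values cannot decide whether a GC trend made GC-rich genes pass more often. Whether genes that fall are still GC-rich after the removal was not tested. With the young control footprint libraries counted as 1 sample 52.2% were called lower at a median of −2.25, so the part played by the small spread of those libraries stays open. The fall was in footprints (median −1.91), with RNA at 0.31. A lower use of these mRNAs by ribosomes may remain as a hypothesis, as does a difference in how footprints were recovered, which was not tested.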

How the results depend on the processing

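The tests with the GC trend removed, with the block and that removal together, and with the young control footprint libraries as 1 sample were chosen only after the data were seen. No called value of a named gene changed sign. The majority of calls did turn: RNA heat shock in young cells went from 88 higher and 62 lower to 480 and 676 with the block, 60 and 134 by library size only, 221 and 224 by DESeq2, 70 and 122 on TPM, and 165 and 220 with the GC trend removed. RNA heat shock in senescent cells (48 and 28) turned to 41 and 53 by library size only, 351 and 477 with the block, 126 and 159 by DESeq2 and 81 and 130 with the GC trend removed. Footprint heat shock in young cells (87 and 43) turned to 68 and 169 by library size only, 197 and 225 without the filter, 153 and 209 in the 4 libraries compared, and 130 and 140 or 132 and 143 without senescent heat shock replicate 1 or 2. With the block and the GC trend removed these 3 were 493 and 719, 256 and 437, and 188 and 189. Of 1457 called values of named genes under other settings, 1372 kept their call and 85 lost it, and of 1800 with 1 library left out, 1297 kept it and 503 lost it. With 2 libraries per group, a library left out leaves a lone sample that is assumed to vary like the other groups. For each value below that differs from the report's count the cause was not tested, except where fewer libraries or genes entered the fit.

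Counts are given for heat shock in young, heat shock in senescent, the difference of responses, senescent against young in control, and the same under heat shock. Without a filter on low counts the RNA counts were 317, 163, 2, 74 and 110 and the footprint counts 422, 1528, 5, 118 and 112, and efficiency in control gave 2. With replicate number as a block the RNA counts were 1156, 828, 1, 490 and 1811. Footprints with the block gave 330 and 1667 for heat shock and 27 and 18 for senescent against young, and efficiency gave 57, 1156, 0 and 6. DESeq2 gave 445, 285, 3, 144 and 245 for RNA, 447, 1515, 10, 120 and 143 for footprints and 47, 641, 4 and 6 for efficiency. With the block and the GC trend removed RNA gave 1212, 693, 1, 308 and 645, footprints 377, 1693, 38 (control) and 22 (heat shock), and efficiency 33, 862, 0 and 6. With the GC trend removed RNA gave 385 and 211 for heat shock, 19 in control and 28 under heat shock. Limma-trend on TPM gave 128 for RNA heat shock in senescent cells, 2 for the difference, 3 in control and 6 under heat shock, and 80 for footprints in young cells. In fits of only the 4 libraries compared RNA gave 48 in young cells and 0 in control, and footprints 362 and 270 for heat shock and 1 in control. Library size only gave 0 for RNA in control and 237 for footprints in young cells. For footprints of senescent against young cells under heat shock relative log expression scaling, TPM, GC removal, the 4 libraries compared and the young control libraries as 1 sample each gave 0, where edgeR called 1 and 1463 genes were at an unadjusted p under 0.05. With those control libraries as 1 sample footprints gave 27 and 247 for heat shock and efficiency 5, 146 and, for the difference, 0. Limma voom gave 39 for efficiency in senescent cells, 0 for the difference and 2 in control.

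With an estimated correlation 7 list results were called and with fry 34, of 130 by camera. For the difference of response ER chaperones gave adjusted p = 0.0943 in RNA and 0.691 in footprints with an estimated correlation, and 0.225 and 0.415 by fry, where cytosolic chaperones gave 0.0705 in RNA. In footprints camera at the preset correlation gave cytosolic chaperones adjusted p = 0.0262 with the block, 0.0484 with the GC trend removed and 0.0192 with both. In the main fit that list gave adjusted p = 0.691 with an estimated correlation and 0.409 by fry.

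With 1 library left out, RNA heat shock in young cells gave 33 to 123 calls: 33 without young control replicate 1, 36 without young control replicate 2, 47 and 60 without young heat shock replicates 1 and 2, and 87 and 85 without senescent control replicates 1 and 2. In senescent cells RNA gave 15 to 65: 16 and 15 without senescent control replicates 1 and 2, and 27 and 29 without senescent heat shock replicates 1 and 2. RNA in control gave 0 without any of the 8, and the RNA difference and RNA under heat shock gave 0 throughout. Footprints in young cells gave 27 to 275: 27 without either young control library, 51 without young heat shock replicate 1, 77 without replicate 2, and 270 and 275 without senescent heat shock replicates 1 and 2. In senescent cells footprints gave 237 to 1934: 244 and 249 without young control replicates 1 and 2, 264 and 302 without senescent control replicates 1 and 2, 1934 without senescent heat shock replicate 1 and 237 without replicate 2. The footprint difference gave 0 throughout. Footprints in control gave 0 to 6: 6 without either young heat shock library and 4 without senescent heat shock replicate 1. Under heat shock they gave 0 to 494: 494 without senescent heat shock replicate 1, 3 without young heat shock replicate 2, 1 (another gene, which was higher) without young heat shock replicate 1, and 0 without young control, senescent control or senescent heat shock replicate 2 libraries. Efficiency in young cells gave 5 to 16: 5 without RNA young heat shock, footprint young control or footprint young heat shock replicate 2 libraries, and 16 without either footprint senescent heat shock library. In senescent cells efficiency gave 49 to 668: 49 without footprint senescent heat shock replicate 2, 668 without replicate 1, 50 and 458 without RNA senescent control replicates 1 and 2, 99 without RNA senescent heat shock replicate 2, 145 and 146 without footprint young control replicates 1 and 2, and 141 without footprint senescent control replicate 1. The efficiency difference gave 0 to 2: 2 without footprint young heat shock replicate 2 or senescent control replicate 2, 1 without RNA senescent control replicate 2 or senescent heat shock replicate 2, and 0 without any of the other 12 libraries. Efficiency in control gave 1 to 32: 32 without footprint senescent control replicate 2 and 3 without a footprint library of either heat shock group. For the difference of response the adjusted p in RNA was 8.16e-14 to 2.73e-09 for cytosolic chaperones and 5.08e-14 to 3.02e-04 for ER chaperones. In footprints it was 0.0292 (without senescent heat shock replicate 2; 0.0477 without young heat shock replicate 1) to 0.475 for cytosolic chaperones. For ER chaperones it was 2.34e-04 to 0.421 (without young heat shock replicate 1), with 0.0697 without senescent control replicate 2 and 0.0789 without senescent heat shock replicate 1.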

Other observations

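The tests given here were fixed before their results were seen, apart from that without PABPC1. Ribosomal protein mRNAs carry a terminal oligopyrimidine motif at the start of the mRNA, as do some translation factors, and footprints of ribosomal protein mRNAs lay below their RNA on heat shock. A hypothesis is that mRNAs with the motif may share this. Among 41 translation factors, the 11 with the motif had a lower median change of efficiency than the 30 without it, by −0.54 in young cells (permutation p = 1.50e-04 from 100000 resamples; adjusted 1.50e-04), with 9 of 11 against 7 of 30 below 0. In senescent cells the difference was −1.25 (permutation p = 6.00e-05; adjusted 1.20e-04), with 9 of 11 against 6 of 30 below 0. Without PABPC1, which fell most, the differences were −0.50 (permutation p = 2.60e-04) and −1.14 (permutation p = 7.00e-05). These values are consistent with the hypothesis. The permutations shuffle genes, which are not independent replicates, and whether the motif itself acts was not tested. The hypothesis came from these same libraries, in which falls of PABPC1, PABPC4 and TPT1 are reported above. The tests are thus no independent evidence for it.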
